A study of Homo sapiens with 24 samples.

How the data were processed

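RNA was sequenced from 24 libraries of 2 human breast cancer cell lines, MCF-7 and MDA-MB-231, with 12 libraries per line. The labels place them in 8 groups of 3 libraries, set by cell line, siRNA (scramble or P4HB) and drug (etoposide or interferon-γ), and give no untreated group. Group membership was taken from the labels. Experiment numbers were read as replicate numbers, and a block on them was tried as an alternative.

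The deposited count table lists 58608 RefSeq transcripts in the layout of a featureCounts output, with exon positions and a length in bases for each transcript. Per the submitters' processing notes, reads were mapped to hg38, duplicate reads were removed and DESeq2 was used. The aligner, the software versions, the library preparation and the strand setting are not given in the sources used here. The authors' deposited values are expected counts rather than whole reads: 74.3% of the transcript values above 0 were whole within 0.03, and the rest were fractions. The design fixed at the outset had assumed plain counts. Because a read was counted in full for every transcript it overlapped, the deposited table totals (22.8 to 29.6 M per library) exceed the number of reads. The authors' deposited DESeq2 tables give a mean of normalized counts, a log2 fold change with its standard error in log2 units, a Wald score, a p-value and an adjusted p-value for each significant transcript. They do not state the direction of the contrast. A further table deposited by the authors holds gene symbols in lists per line, drug and direction, with no other values.

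Transcripts were given gene symbols from a RefSeq table (57573 transcripts) or through GENCODE 29 (641 transcripts), and 394 remained without a symbol. Of all counts, 99.8% fell on transcripts with a symbol. Each gene was represented by its transcript with the most counts over the 24 libraries, which left 27394 genes, of which 11542 had more than 1 transcript. Gene counts were rounded to whole numbers. Library totals at gene level ranged from 8.9 to 11.37 M reads, with a mean of 10.29 M. The strand of the reads is unknown. Some genes with close copies, or with a large part of their sequence shared with another gene, are marked as uncertain in the text, and others that share some reads with a copy are named without a mark.

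Gene expression was compared with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter by group and the quasi-likelihood F-test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. The 4 groups of a line were fitted together for comparisons within that line (15520 genes in MCF-7, 15447 in MDA-MB-231), and all 24 libraries for comparisons between lines (17101 genes). The 11 comparisons were P4HB siRNA against scramble in each line and drug, the difference of that effect between drugs in each line and between lines under each drug, etoposide against interferon-γ in scramble cells of each line, and the difference of that contrast between lines. Differences between drugs are etoposide minus interferon-γ, and differences between lines are MCF-7 minus MDA-MB-231. Tables of transcript levels hold CPM (reads per M reads of the library), given as means with the SD over 3 libraries. Fold changes are on the log2 scale with their SE. The p-values measure the spread between libraries, which may be technical, since the sources used here do not say whether the replicates were separate cultures.

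The comparisons, the tests, 23 gene lists and the rule for named genes were fixed before the data were examined. The lists cover the PDI family, ER chaperones, ATF4 and CHOP targets, collagens and their hydroxylases, p53 targets, interferon gamma targets, MHC class I antigen presentation, type I interferon-stimulated genes, oestrogen receptor targets, mesenchymal markers, G1/S and DNA replication, G2/M and mitosis, apoptosis regulators, cholesterol biosynthesis, NRF2 targets, hypoxia and glycolysis, NF-kB and inflammatory secretion, DNA repair, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, and myeloid and lymphoid or fibroblast and endothelial markers of other cell types. P4HB is in none of them. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation.

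Named genes are P4HB, and, for each siRNA and each drug comparison, the 8 largest changes in each direction among called genes with a mean log2 CPM of at least 1 and no overlap between the 3 and 3 libraries. Chance alone gives no overlap for 10% of genes with 3 libraries against 3. Up to 4 members of each list with the smallest adjusted p, and the 5 smallest adjusted p per direction for each difference between lines or drugs, were also named. Genes without a symbol and pseudogenes were skipped. List members that moved against the rest of their list were named after their values were seen.

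The alternatives named at the outset were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of at least 50 reads in 3 libraries, a replicate block, leaving out each library in turn, a fit of only the 6 libraries compared, a fit of all 24 libraries and the estimated correlation. After the data had been seen, 4 were added: counts summed over a gene's transcripts, the longest transcript of each gene, only genes under 0.3 reads per base, and an edgeR likelihood ratio test. That last test does not let the variance fall under that of read counting. The pipeline was tested on simulated data built from the files, in which genes with a log2 change of 0.25, 0.5 and 1 were recovered in 47.8%, 79.1% and 95.5% of cases in MCF-7 and in 58.2%, 76.1% and 93.9% in MDA-MB-231. False calls were 4.5% and 9.5% of the calls. The simulated counts could not vary less than read counting allows, while many genes in the data did. Few genes were changed, so these rates may not hold for the data. The mitochondrially encoded mRNAs were left out, since 0 of them passed the filter in any comparison.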

Results

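The transcriptomes of MCF-7 and MDA-MB-231 cells were profiled after knockdown of P4HB, the gene of protein disulfide isomerase A1, an endoplasmic reticulum enzyme that forms and rearranges disulfide bonds. MCF-7 is an oestrogen receptor positive breast cancer line with wild-type TP53, and MDA-MB-231 is an oestrogen receptor negative line with mutated TP53, per the labels. Cells carried scramble or P4HB siRNA (5 µM, 72 h). They received either etoposide (10 µM, 24 h), a topoisomerase II poison that breaks DNA, or interferon-γ (10 ng/ml, 24 h), a cytokine that induces antigen presentation. Each of the 8 groups held 3 libraries. Library totals at gene level were 8.9 to 10.37 M reads in the MCF-7 scramble etoposide group, the lowest, and 10.44 to 11.37 M reads in the MDA-MB-231 P4HB siRNA interferon-γ group, the highest. The study's title names PDIA1-associated pathways and stratified breast cancer therapy as its subject. The comparisons ask what P4HB knockdown changes in each line under each drug, whether that change differs between drugs or lines, and how the drugs differ in scramble cells.

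P4HB itself (NM_000918, hg38, chromosome 17, 81843158 to 81860668, minus strand, 11 exons) was lower in each of the 12 knockdown libraries than in every scramble library of the same line and drug. In MCF-7 with etoposide its level was 100.7 ± 4.5 CPM (SD, n = 3) against 190.8 ± 8.6 in scramble, or 52.3% remaining. With interferon-γ it was 106 ± 4.6 against 185.4 ± 3.8 CPM, or 56.8% remaining. MDA-MB-231 kept more of the transcript, at 123.7 ± 2.7 against 181.6 ± 7.6 CPM with etoposide (68.4%) and 137.8 ± 18.5 against 188.5 ± 6 CPM with interferon-γ (73.1%). Knockdown library 3 of that last group stood at 159.2 CPM. Duplicate reads were removed, which may cap the counts of genes with many reads per base and compress their fold changes. Over the 24 libraries ACTB and GAPDH, at 1.3 and 1.58 reads per base, averaged 229.5 and 227.9 CPM, and P4HB, at 0.6, averaged 151.8. The share of P4HB remaining may therefore be overstated, which was not tested. The log2 changes were -0.94 ± 0.04 and -0.82 ± 0.04 (SE) in MCF-7 (adjusted p = 2.71e-09 and 8.67e-09) and -0.55 ± 0.07 and -0.45 ± 0.07 in MDA-MB-231 (adjusted p = 0.0109 and 0.0329). The knockdown was deeper in MCF-7 by -0.37 ± 0.08 with etoposide (adjusted p = 0.0122) and by -0.36 ± 0.08 with interferon-γ (adjusted p = 0.03). Between the drugs the P4HB knockdown differed by -0.12 ± 0.06 in MCF-7 (adjusted p = 0.949) and -0.10 ± 0.09 in MDA-MB-231 (adjusted p = 0.99), which did not pass. In scramble cells the P4HB level also did not pass between the drugs, at 0.02 ± 0.04 in MCF-7 (adjusted p = 0.711) and -0.05 ± 0.06 in MDA-MB-231 (adjusted p = 0.534).

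**Figure D1:**
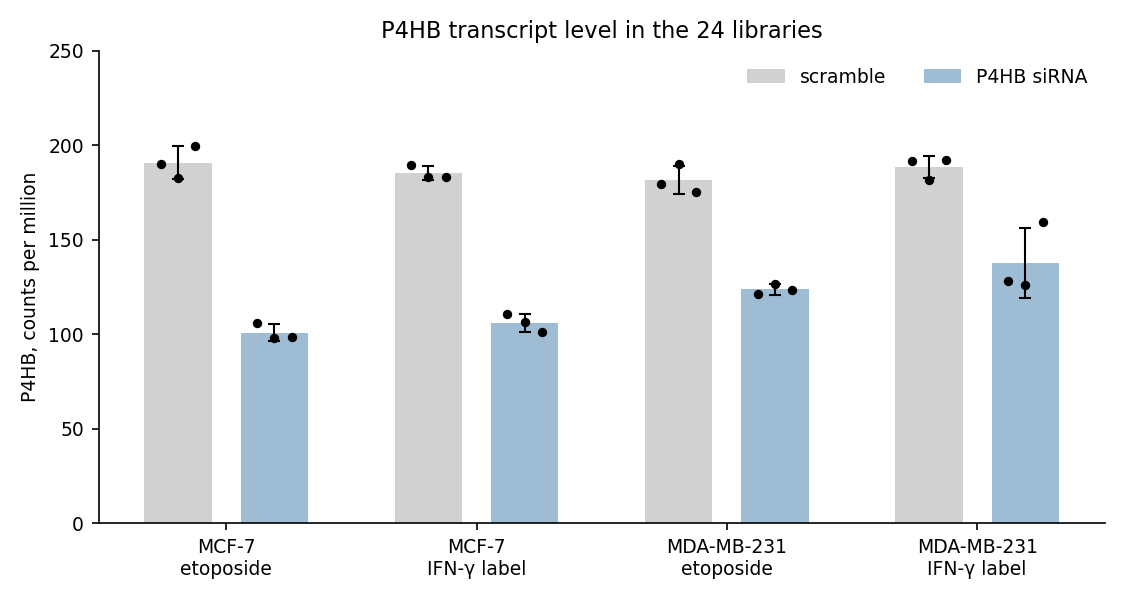
P4HB level in CPM in the 24 libraries (points), with the mean (bars) and SD (error bars) of 3 libraries per group. P4HB siRNA groups average 100.7 to 137.8 and scramble groups 181.6 to 190.8.

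In MCF-7 cells treated with etoposide, all 28 genes of the G2/M and mitosis list fell with P4HB siRNA, by a median log2 change of -0.45. CDCA8, a chromosomal passenger protein, changed by -0.53 ± 0.05 (adjusted p = 6.67e-06), the mitotic kinesin KIF20A by -0.51 ± 0.05 (adjusted p = 6.69e-06), and CDC20, an activator of the anaphase-promoting complex, by -0.41 ± 0.04 (adjusted p = 1.26e-05). The cystine transporter SLC7A11 fell from 62.7 ± 11 to 31.5 ± 4.4 CPM (SD, n = 3). In the opposite direction, COL3A1, a fibrillar collagen, rose by 0.76 ± 0.11 (adjusted p = 0.000282) and the aldo-keto reductase AKR1C2 by 0.60 ± 0.05 (adjusted p = 4.25e-06). Of 15520 genes tested, 1177 rose and 1011 fell in edgeR, with a median size of 0.26, and 65 changed over 2-fold.

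The largest rises were in TP63, a transcription factor of basal epithelium (1.71 ± 0.25, adjusted p = 0.000266), the aldehyde dehydrogenase ALDH3A1 (1.45 ± 0.21, adjusted p = 0.000213), the antisense RNA SSTR5-AS1 (1.42 ± 0.15), MYEOV (1.33 ± 0.20), the antisense RNA ITGB2-AS1 (1.30 ± 0.22), STUM (1.24 ± 0.16), the Cdc42 effector CDC42EP3 (1.22 ± 0.21) and the aldo-keto reductase AKR1B10 (1.20 ± 0.21). The values of SSTR5-AS1, ITGB2-AS1 and AKR1B10 are uncertain, since reads could come from the opposite strand or from copies of the gene. TP63 stood at 3.4 ± 0.88 CPM against 1.02 ± 0.1 in scramble. The largest falls were in the secreted protein NELL2 (-1.30 ± 0.12, adjusted p = 7.31e-06), the peptide hormone APELA (-1.17 ± 0.22), the immune checkpoint ligand VTCN1 (-1.17 ± 0.29), the nuclear receptor NR4A3 (-1.15 ± 0.13, adjusted p = 2.86e-05), the formin DAAM2 (-1.07 ± 0.29), SLC7A11 (-1.01 ± 0.12, adjusted p = 3.56e-05) and the endocytic receptor LRP2 (-0.95 ± 0.17). P4HB was the eighth.

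The G2/M list passed in camera (adjusted p = 6.62e-44), and adjusted p = 0.125 with an estimated correlation. Of 28 G1/S and DNA replication genes, 16 fell, or 24 adjusted over the list alone, among them the transcription factor E2F1 (-0.39 ± 0.05) and the ribonucleotide reductase subunit RRM2 (-0.32 ± 0.04, uncertain). This list passed at adjusted p = 6.96e-16, with adjusted p = 0.137 with an estimated correlation. Among 27 DNA repair genes, 11 fell, or 16 adjusted over the list alone, including the recombination factor RAD54L (-0.41 ± 0.06) and the Fanconi anaemia genes FANCD2 (-0.25 ± 0.04) and FANCI (-0.26 ± 0.04). Its adjusted p was 1.21e-08, with adjusted p = 0.166 with an estimated correlation. Of the 53 replication-dependent histones, 9 fell, H2BC21 by -0.16 ± 0.03 among them (list adjusted p = 0.00468, or adjusted p = 0.336 with an estimated correlation). Histone genes are uncertain because their sequences are nearly alike.

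Of 21 collagen and hydroxylase genes 8 rose and 0 fell in edgeR, with COL5A2 at 0.45 ± 0.06, COL5A1 at 0.42 ± 0.06 and COL4A5 at 0.27 ± 0.04 (list adjusted p = 0.000159, or adjusted p = 0.125 with an estimated correlation). In the MHC class I list 7 of 15 rose, among them the peptide transporter genes TAP1 (0.22 ± 0.05) and TAP2 (0.32 ± 0.07), while none fell in edgeR (list adjusted p = 0.00468, or adjusted p = 0.137 with an estimated correlation). Mesenchymal markers rose in 6 of 20, with the growth factor receptor EGFR at 0.79 ± 0.13 and fibronectin FN1 at 0.40 ± 0.05, against a fall of THBS1 (-0.17 ± 0.03), a matrix glycoprotein (list adjusted p = 0.00171, or adjusted p = 0.166 with an estimated correlation). Of 33 p53 targets 8 rose, including TP53INP1 (0.18 ± 0.02) and SPATA18 (0.25 ± 0.04), whereas MDM2 (-0.12 ± 0.03), which degrades p53, and KITLG (-0.17 ± 0.04), a growth factor, fell (list adjusted p = 0.00519, or adjusted p = 0.137 with an estimated correlation). ATF4 and CHOP targets fell in 7 of 26, SLC7A11, SLC7A5 (-0.19 ± 0.03) and the serine synthesis enzyme PHGDH (-0.26 ± 0.04) among them, and SESN2, a stress-induced inhibitor of mTORC1, rose (list adjusted p = 0.000888, or adjusted p = 0.137 with an estimated correlation). For cholesterol biosynthesis 4 of 23 fell, such as IDI1 (-0.13 ± 0.03), and STARD4, a sterol carrier, rose by 0.43 ± 0.08 (list adjusted p = 0.0275, or adjusted p = 0.497 with an estimated correlation).

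The remaining lists did not pass. NRF2 targets split (adjusted p = 0.642), with 5 of 23 higher, the drug exporters ABCC2 (0.88 ± 0.09) and ABCC3 (0.78 ± 0.06) and the 3 aldo-keto reductases, and 3 lower, SLC7A11, GCLM and HMOX1. AKR1C1 and AKR1C2 share reads and are uncertain. The median of this list was -0.05 while its mean was 0.09 and its test pointed up. The medians and means also had opposite signs for the type I interferon-stimulated genes (-0.10 and 0.01, test down), hypoxia and glycolysis (-0.05 and 0.02, test down) and inflammatory secretion (-0.02 and 0.06, test up). Apoptosis regulators had 0 rises and 4 falls in 24 (adjusted p = 0.0623), and the inhibitors XIAP (-0.31 ± 0.04) and BCL2 (-0.62 ± 0.11) were among them. None of 25 PDI family genes passed in edgeR (list adjusted p = 0.566). ER chaperones had 2 of 27 higher, SEC24D (0.19 ± 0.03) and the chaperone HSPA5 (0.11 ± 0.03), and DERL1 lower (list adjusted p = 0.566). Interferon gamma targets showed GBP3 higher (0.89 ± 0.24) and LAP3 lower (-0.13 ± 0.03) of 17 tested (list adjusted p = 0.543). Type I interferon-stimulated genes fell in 2 of 24, EIF2AK2 and HERC5 (list adjusted p = 0.233). Oestrogen receptor targets had SERPINA1 and AREG higher and GREB1 lower of 28 (list adjusted p = 0.144). In the hypoxia and glycolysis list PFKFB3 and ANGPTL4 rose and ALDOC and NDRG1 fell, of 22 (list adjusted p = 0.309). The cytokine LIF rose by 0.63 ± 0.06 as the 1 change in 10 genes of inflammatory secretion (list adjusted p = 0.368). RPS3 (uncertain) was the 1 fall in 82 ribosomal protein genes (list adjusted p = 0.0706). Among the fibroblast and endothelial markers, ACTA2 (uncertain) and TAGLN rose of 5 tested (list adjusted p = 0.212), and the 2 myeloid and lymphoid markers tested, ITGAM and CD68, did not pass and were too few for a list test.

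**Figure D2:**
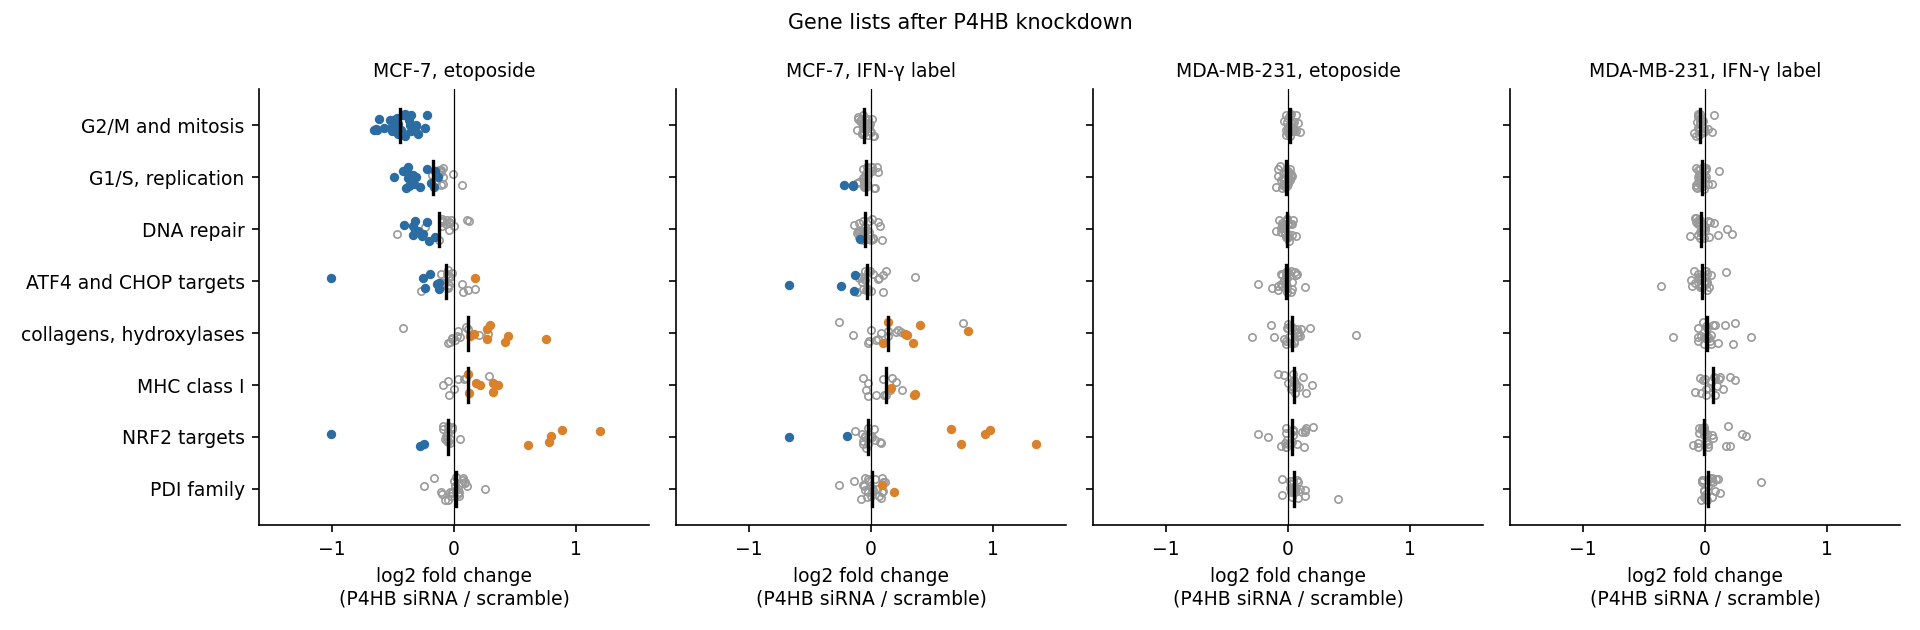
Log2 fold change of P4HB siRNA over scramble for each tested gene of 8 lists in the 4 knockdown comparisons; filled points passed an adjusted p of 0.05 (orange higher, blue lower), open points did not, and black bars are medians. The G2/M median is -0.45 in MCF-7 with etoposide and -0.06 in MCF-7 with interferon-γ, and no list gene passed in MDA-MB-231.

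DESeq2 called 961 genes in this comparison against 2188 by edgeR. Without P4HB siRNA library 3, 1319 genes passed.

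In MCF-7 cells with interferon-γ, P4HB siRNA raised SERPINE1, the plasminogen activator inhibitor, from 1.06 ± 0.18 to 3.72 ± 0.25 CPM (SD, n = 3), a log2 change of 1.79 ± 0.27 (adjusted p = 0.000483). NR4A3 fell by 1.40 on the log2 scale (SE 0.15, adjusted p = 2.85e-05) and CALCR, the calcitonin receptor, from 86.7 ± 2.4 to 43.1 ± 2.4 CPM (-1.02 ± 0.04, adjusted p = 1.65e-09). EGFR rose by 0.97 ± 0.11 (adjusted p = 4.54e-05) and COL3A1 by 0.80 ± 0.09 (adjusted p = 4.54e-05). None of the 28 G2/M genes passed in edgeR. In all, 911 genes rose and 601 fell, and 56 changed over 2-fold.

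Further large rises were FBLN2, a matrix protein (1.40 ± 0.20), the pentraxin NPTX1 (1.40 ± 0.23), MALL (1.39 ± 0.10, uncertain because of a copy), AKR1B10 (1.36 ± 0.21, uncertain), ALDH3A1 (1.35 ± 0.24), the surface antigen LY6D (1.35 ± 0.23) and the dynamin DNM3 (1.23 ± 0.23). Falls included the methionine adenosyltransferase MAT1A (-1.31 ± 0.20), VTCN1 (-1.28 ± 0.33), NELL2 (-1.20 ± 0.12, adjusted p = 2.02e-05), EPDR1 (-1.13 ± 0.20) and LINC00689 (-1.13 ± 0.27). CPLX3 fell by 1.00 on the log2 scale (SE 0.23). Collagens and hydroxylases rose in 7 of 21, or 11 adjusted over the list alone with 1 lower, and P3H1, a prolyl hydroxylase, was at 0.29 ± 0.05 (list adjusted p = 2.18e-05, or adjusted p = 0.103 with an estimated correlation). The mesenchymal list had 5 of 20 higher and THBS1 (-0.20 ± 0.03) and CCN1, a matrix signalling protein, lower (list adjusted p = 0.016, or adjusted p = 0.465 with an estimated correlation). MHC class I genes rose in 3 of 15, HLA-F (0.35 ± 0.08, uncertain), TAPBPL and ERAP1, or 8 adjusted over the list alone (list adjusted p = 0.016, or adjusted p = 0.256 with an estimated correlation). Of 33 p53 targets 6 rose and MDM2 and KITLG fell (list adjusted p = 0.016, or adjusted p = 0.256 with an estimated correlation). The aldo-keto reductases and ABCC2 (0.98 ± 0.08) and ABCC3 (0.66 ± 0.07) again rose, giving 5 higher and 2 lower, SLC7A11 and GCLM, of 23 NRF2 targets, with a median of -0.02, a mean of 0.15 and an upward test (list adjusted p = 0.0535). XIAP (-0.29 ± 0.04), PMAIP1 (-0.50 ± 0.08), BCL2 (-0.57 ± 0.09) and CFLAR (-0.15 ± 0.04) fell among 24 apoptosis regulators (list adjusted p = 0.0545). Of 26 ATF4 and CHOP targets 4 fell, SLC7A11 by 0.67 (SE 0.11) on the log2 scale (list adjusted p = 0.0222, or adjusted p = 0.465 with an estimated correlation).

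The G2/M list had a median of -0.06 (adjusted p = 0.0368, or adjusted p = 0.693 with an estimated correlation), and the G1/S list 3 falls of 28, CCNE2, E2F1 and CLSPN (adjusted p = 0.016, or adjusted p = 0.666 with an estimated correlation). DNA repair showed FANCA (uncertain) alone lower of 27 (adjusted p = 0.0222, or adjusted p = 0.641 with an estimated correlation), and oestrogen receptor targets SERPINA1 higher and ELF3 lower of 28 (adjusted p = 0.0209, or adjusted p = 0.641 with an estimated correlation). Altogether 9 of 21 lists passed and 0 with an estimated correlation, against 10 and 0 with etoposide. DESeq2 called 592 genes against 1512 by edgeR. Leaving out scramble library 3 gave 951 genes and leaving out P4HB siRNA library 2 gave 849.

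The 2 MCF-7 comparisons share no library. Of the genes called, 613 rose in both, against 69.1 expected from independent lists, and 387 fell in both, against 39.2 expected, with 0 in opposite directions in edgeR (4179 and 3566 genes had an unadjusted p under 0.05). Across 15520 genes the log2 changes had a Pearson correlation of 0.55 and a Spearman correlation of 0.55; genes are not independent replicates. FYCO1, an adaptor of autophagosome transport (NM_024513, hg38, chromosome 3, 45917899 to 45995824), rose in both, by 0.61 ± 0.04 (adjusted p = 2.03e-07) and 0.50 ± 0.04 (adjusted p = 2.17e-06). NELL2, NR4A3, VTCN1 and SLC7A11 fell in both. DESeq2 shared 423 genes between the drugs, where edgeR shared 1000.

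In MDA-MB-231 cells few genes passed. With etoposide FYCO1 rose from 79.2 ± 4 to 99.1 ± 4.3 CPM (SD, n = 3), by 0.33 ± 0.05 (adjusted p = 0.0274), and P4HB fell. With interferon-γ FYCO1 rose by 0.37 ± 0.04 (adjusted p = 0.01) and the protocadherin PCDH7 (NM_001173523, hg38, chromosome 4, 30720415 to 31146801) from 15.5 ± 0.45 to 23 ± 2.2 CPM, by 0.57 ± 0.08 (adjusted p = 0.0254), and P4HB fell. That makes 2 and 3 of 15447 genes, with 1099 and 1374 at an unadjusted p under 0.05. FYCO1 and P4HB were the 2 genes called under both drugs. With a block on the experiment number 0 genes were called under both in edgeR, since FYCO1 with etoposide (adjusted p = 0.075) and P4HB with interferon-γ (adjusted p = 0.0854) did not pass. Across genes the log2 changes under the drugs had a Pearson correlation of 0.13, with genes not independent replicates.

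SLC7A11 had a value of -0.24 ± 0.04 with etoposide (adjusted p = 0.0785) and did not pass. CALCR was at -1.66 ± 0.34 (adjusted p = 0.114) and -0.99 ± 0.41 (adjusted p = 0.51), at levels of 3.39 ± 0.5 CPM or less. No list gene passed over all genes under either drug in edgeR. As sets, 5 lists passed upward with etoposide: the PDI family (median 0.05, adjusted p = 0.000115), ER chaperones (0.06, adjusted p = 6.44e-05), interferon gamma targets (0.06, adjusted p = 0.000138), MHC class I (0.05, adjusted p = 0.00106) and type I interferon-stimulated genes (0.03, adjusted p = 0.0219). With an estimated correlation the adjusted p was 0.59 for the PDI family, the interferon gamma targets and MHC class I, 0.708 for ER chaperones and 0.786 for the interferon-stimulated genes. PDIA4, a PDI family member, had a value of 0.14 ± 0.04 (adjusted p = 0.357). With interferon-γ 9 lists passed, and 1 with an estimated correlation: the 8 fibroblast and endothelial markers, with a median of 0.24, 8 of 8 positive (adjusted p = 0.000188, or adjusted p = 0.0456 with an estimated correlation). Of these PECAM1 had 0.37 ± 0.09 (adjusted p = 0.249) and TAGLN 0.24 ± 0.09 (adjusted p = 0.476). The other 8 were the interferon gamma targets (median 0.10, adjusted p = 9.93e-05), type I interferon-stimulated genes (0.09, adjusted p = 0.00102), MHC class I (0.06), ribosomal proteins (0.03) and the PDI family (0.03) upward, and G2/M (-0.04, adjusted p = 0.00102), G1/S (-0.03) and ATF4 and CHOP targets (-0.03) downward. The adjusted p of these with an estimated correlation was 0.579, and 0.679 for ribosomal proteins. Without P4HB siRNA library 3, the one with 159.2 CPM of P4HB, 4 lists passed.

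By DESeq2, 13 and 5 genes passed in the MDA-MB-231 comparisons, and without P4HB siRNA library 3 of each group 74 and 11 passed in edgeR. Both P4HB calls were lost in some fits with 1 library left out, with adjusted p up to 0.114 with etoposide without scramble library 2 and up to 0.239 with interferon-γ without scramble library 3. Without scramble library 3, FYCO1 did not pass with etoposide (0.32, adjusted p = 0.138) or with interferon-γ (0.35, adjusted p = 0.171), and PCDH7 did not pass with interferon-γ (0.55, adjusted p = 0.239). No gene passed in edgeR in some of these fits, such as the one without P4HB siRNA library 1 of either drug.

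The knockdown changes were compared between the drugs within each line. In MCF-7, the log2 change with knockdown was lower with etoposide than with interferon-γ for mitotic genes: the kinesin KIF4A by -0.59 ± 0.07, GTSE1 by -0.59 ± 0.07, CDC20 by -0.42 ± 0.05, PIMREG by -0.84 ± 0.11 and DEPDC1 by -0.65 ± 0.09, each at adjusted p = 0.00296. CDC20 went from 61.2 ± 1.6 to 46.6 ± 2.1 CPM with etoposide and from 86.3 ± 2.1 to 87.7 ± 1.5 CPM with interferon-γ (SD, n = 3). RGS6, a regulator of G protein signalling, was the 1 gene with a higher knockdown effect under etoposide (0.69 ± 0.12, adjusted p = 0.0142), against 68 with a lower one. KIF4A and DEPDC1 have copies elsewhere in the genome and are uncertain. Of 28 G2/M genes 16 differed downward, or 28 adjusted over the list alone, with a median of -0.41 (camera adjusted p = 4.95e-85, or adjusted p = 0.0181 with an estimated correlation). The G1/S list had 2 lower genes, MCM10 and E2F2, or 14 adjusted over the list alone (adjusted p = 2.09e-21, or adjusted p = 0.203 with an estimated correlation). DNA repair had none lower in edgeR over all genes and 9 adjusted over the list alone (adjusted p = 6.81e-09, or adjusted p = 0.378 with an estimated correlation).

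In MDA-MB-231 no gene differed between the drugs in edgeR or in DESeq2, with 714 and 259 at an unadjusted p under 0.05. The G2/M list had a median of 0.06 (adjusted p = 2.31e-05, or adjusted p = 0.858 with an estimated correlation), ribosomal proteins -0.04 (adjusted p = 0.0143, or adjusted p = 0.858 with an estimated correlation) and fibroblast and endothelial markers -0.23 (adjusted p = 0.00884, or adjusted p = 0.181 with an estimated correlation). The MCF-7 count of 69 moved to 39 to 122 when single libraries were left out. In MDA-MB-231, 90 genes passed without P4HB siRNA etoposide library 3.

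Between the lines, the knockdown with etoposide differed in 556 of 17101 genes, 332 with a higher and 224 with a lower effect in MCF-7. The higher effects in MCF-7 with the smallest adjusted p were in the protease CAPN2 by 0.62 ± 0.06 (adjusted p = 2.19e-06), the collagen-crosslinking enzyme LOXL2 by 1.12 ± 0.12, the laminin chain LAMB3 by 0.85 ± 0.10, the ERK phosphatase DUSP5 by 0.80 ± 0.09 and the TGF-β receptor TGFBR2 by 0.50 ± 0.06. In scramble cells with etoposide each of these stood lower in MCF-7 than in MDA-MB-231, LOXL2 at 4.44 against 182 CPM and DUSP5 at 13.7 against 86.1. The changes thus start from unlike levels. Mitotic genes had the lower effect: the spindle protein SPAG5 (-0.50 ± 0.05, adjusted p = 2.19e-06), KIF4A (-0.66 ± 0.07, uncertain), CDCA8 (-0.51 ± 0.05), KIF23 (-0.39 ± 0.04) and KIF20A (-0.59 ± 0.06). All 28 G2/M genes differed downward, with a median of -0.45 (adjusted p = 3.61e-83, or adjusted p = 0.00112 with an estimated correlation). The mesenchymal list had 7 of 26 higher and 0 lower in edgeR, such as EGFR and FN1 (adjusted p = 1.16e-05, or adjusted p = 0.162 with an estimated correlation), and G1/S 10 of 28 lower (adjusted p = 1.46e-18, or adjusted p = 0.0515 with an estimated correlation). DNA repair had 5 of 27 lower (adjusted p = 1.32e-08, or adjusted p = 0.0897 with an estimated correlation). Altogether 9 of 22 lists passed, and 1 with an estimated correlation. Without scramble library 1 or P4HB siRNA library 1 of MDA-MB-231 with etoposide, 5 passed.

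With interferon-γ the knockdown differed between the lines in 200 genes, 156 higher and 44 lower in MCF-7. LAMB3 (1.00 ± 0.10, adjusted p = 4.47e-06), DUSP5 (0.72 ± 0.08), TGFBR2 (0.56 ± 0.06), the ETS factor ETV5 (0.92 ± 0.10) and CAPN2 (0.54 ± 0.06) had the higher effect. RAB30 (-0.59 ± 0.08, adjusted p = 0.000105), FILIP1L (-0.64 ± 0.10), the angiomotin-like AMOTL1 (-0.30 ± 0.05), PHLDB2 (-0.62 ± 0.10) and FAM234B (-0.38 ± 0.06) had the lower. The named genes with the higher effect again stood lower in MCF-7 scramble cells, such as ETV5 at 10.7 CPM against 147 in MDA-MB-231. No G2/M gene differed in edgeR (list median 0.00, adjusted p = 0.895). Mesenchymal genes differed upward in 5 of 26 (adjusted p = 0.000139, or adjusted p = 0.28 with an estimated correlation), SERPINE1 by 1.82 among them, and collagens and hydroxylases in 1, P3H1 (adjusted p = 0.0037, or adjusted p = 0.28 with an estimated correlation). Altogether 6 lists passed and 0 with an estimated correlation. Across 13886 genes tested in both lines, the knockdown changes of MCF-7 and MDA-MB-231 had a Pearson correlation of 0.16 with etoposide and 0.19 with interferon-γ, with genes not independent replicates. The first count fell to 348 without MCF-7 P4HB siRNA etoposide library 3. The second fell to 126 and 109 without MCF-7 scramble interferon-γ libraries 2 and 3, and to 117 and 128 without P4HB siRNA libraries 2 and 3.

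**Figure D3:**
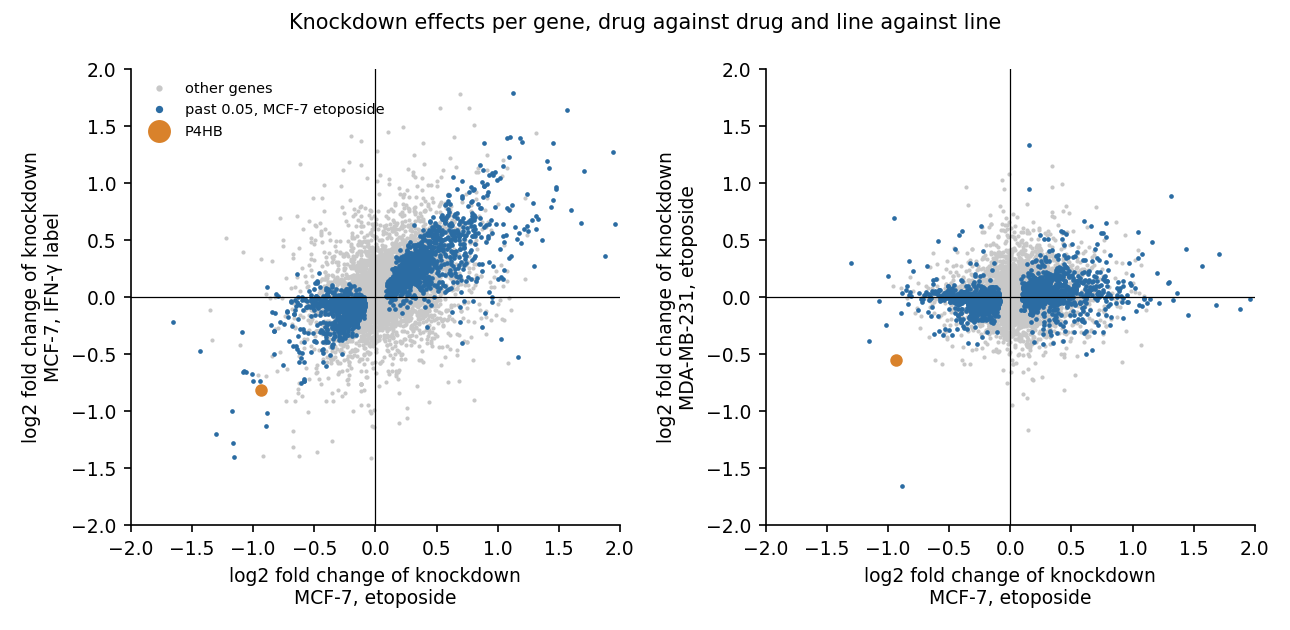
Log2 fold change of P4HB siRNA over scramble per gene in MCF-7 with etoposide (horizontal) against MCF-7 with interferon-γ (left, 15520 genes) and MDA-MB-231 with etoposide (right, 13886 genes), with 2 genes of the left panel outside the axes. Genes called in MCF-7 with etoposide are blue and P4HB is orange; the Pearson correlations across genes are 0.55 and 0.16.

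The drugs were compared in scramble cells, where each can be seen only against the other. In MCF-7, p53 targets were higher and cell cycle and DNA repair genes lower with etoposide than with interferon-γ. Of 33 p53 targets 28 rose and 0 fell in edgeR, 32 adjusted over the list alone, with a median of 0.31 (adjusted p = 1.07e-28, or adjusted p = 0.000172 with an estimated correlation): TP53INP1 by 0.77 ± 0.03 (adjusted p = 6.24e-11), SPATA18 by 0.95 ± 0.04, the antiproliferative gene BTG2 by 0.78 ± 0.04 and the death receptor EDA2R by 0.67 ± 0.05. All 28 G1/S genes fell (median -0.57, adjusted p = 1.41e-47, or adjusted p = 0.0211 with an estimated correlation), with E2F2 at -1.24 ± 0.06 and the methylation factor UHRF1 at -0.96 ± 0.04. All 28 G2/M genes fell as well (median -0.57, adjusted p = 1.71e-38, or adjusted p = 0.0474 with an estimated correlation), with the kinase gene AURKB at -0.67 ± 0.04. DNA repair genes fell in 21 of 27, RAD54L by -1.04 ± 0.05 and BLM by -0.85 ± 0.05, while LIG4, a ligase of end joining, and TOP2B, a topoisomerase, rose (list adjusted p = 3.22e-19, or adjusted p = 0.0474 with an estimated correlation).

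Over all genes 1953 were higher and 2378 lower with etoposide in MCF-7, and 205 changed over 2-fold. The balance of directions depended on the fit, with 2190 higher and 2034 lower when all 24 libraries were fitted together. The largest rises were the transglutaminase TGM2 (2.05 ± 0.21, adjusted p = 2.04e-06), PGLYRP2 (2.01 ± 0.23), DHRS3 (1.66 ± 0.14), the cytidine deaminase APOBEC3H (1.49 ± 0.14), ANGPT4 (1.45 ± 0.20), the neurotrophic factor GDNF (1.39 ± 0.14), LY6D (1.34 ± 0.23) and ACTA2 (1.33 ± 0.11). ACTA2 shares 35.5% of its bases with FAS and an antisense RNA and is uncertain, and FAS itself rose by 1.06. The largest falls were the receptor GPR19 (-1.84 ± 0.25, adjusted p = 3.53e-05), PRIMA1 (-1.83 ± 0.21), MAT1A (-1.79 ± 0.22), the synaptonemal protein SYCE2 (-1.62 ± 0.29), MIR924HG (-1.61 ± 0.15), GNG4 (-1.45 ± 0.21), BRINP3 (-1.45 ± 0.18) and ACTL8 (-1.45 ± 0.27). Interferon gamma targets were not higher in the libraries labelled interferon-γ: 5 of 17 tested were higher with etoposide, HLA-DRB1 by 0.39 ± 0.04 (uncertain) and PARP14 by 0.53 ± 0.06, and 0 lower in edgeR (list adjusted p = 0.045, or adjusted p = 0.244 with an estimated correlation). STAT1 was at 183 ± 5.9 CPM with etoposide and 172 ± 1.2 with interferon-γ, and IRF1 at 18.4 ± 0.27 and 17.3 ± 0.51. Mesenchymal markers fell in 10 of 20, among them CAV1, which fell by 1.00 (SE 0.09), and TGFBI, an extracellular matrix protein, rose (list adjusted p = 0.0435, or adjusted p = 0.351 with an estimated correlation). The chemokine CXCL12, an oestrogen receptor target, fell by 1.17 on the log2 scale (SE 0.08).

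In MDA-MB-231 the drug contrast took another form: type I interferon-stimulated genes were higher with etoposide in 21 of 29 and lower in 0 by edgeR (median 0.47, adjusted p = 4.98e-10, or adjusted p = 0.15 with an estimated correlation). OAS3 rose by 0.61 ± 0.04 (adjusted p = 5.97e-08), OAS2 by 0.58 ± 0.06 and the transcription factor IRF7 by 0.73 ± 0.09. Interferon gamma targets rose in 14 of 30, APOL1 by 0.63 ± 0.06 and GBP2 by 0.34 ± 0.04, and CD274, the ligand of PD-1, was the 1 lower gene, at 74.8 ± 1.6 against 86.5 ± 1.9 CPM (list adjusted p = 0.000297, or adjusted p = 0.264 with an estimated correlation). G1/S genes rose in 16 of 28, E2F2 by 1.15 ± 0.05 and the cyclin CCNE2 by 0.62 ± 0.04, and MCM5, POLA1 and UHRF1, all of DNA replication or its chromatin, fell (list adjusted p = 2.97e-07, or adjusted p = 0.15 with an estimated correlation). G2/M genes fell in 23 of 28, PLK1 by -0.51 ± 0.03 and CDC20 by -0.34 ± 0.03 (list adjusted p = 1.11e-11, or adjusted p = 0.15 with an estimated correlation). Of 31 p53 targets 16 rose, the cell cycle inhibitor CDKN1A by 0.40 ± 0.04 and FDXR by 0.62 ± 0.07, and TNFRSF10B, AEN, PLK2 and CCNG1 fell, 2 of them (TNFRSF10B and AEN) genes of apoptosis (list adjusted p = 0.00079, or adjusted p = 0.0971 with an estimated correlation).

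Mesenchymal markers fell in 19 of 26 in MDA-MB-231, EGFR by -0.48 ± 0.05 and the transcription factor ZEB1 by -0.43 ± 0.04, and SPARC, a matrix protein, rose (list adjusted p = 6.38e-06, or adjusted p = 0.239 with an estimated correlation). E-cadherin CDH1 rose from 1.18 ± 0.57 CPM with interferon-γ to 5.49 ± 1.2 with etoposide (2.20 ± 0.35, adjusted p = 0.000162). Hypoxia and glycolysis genes fell in 15 of 23, PDK1 by -0.54 ± 0.07, with 0 higher in edgeR (list adjusted p = 0.00295, or adjusted p = 0.382 with an estimated correlation). The PDI family fell in 13 of 22, ERO1A by -0.19 ± 0.03, and TMX4 and ERO1B, both oxidoreductases of the same compartment, rose (list adjusted p = 0.0307, or adjusted p = 0.505 with an estimated correlation). Collagens and hydroxylases fell in 11 of 24, COL13A1 by -0.42 ± 0.05, and rose in 4, COL1A1 by 0.76 ± 0.09 (list adjusted p = 0.0301, or adjusted p = 0.382 with an estimated correlation). Of 82 ribosomal protein genes 14 fell, with a median of -0.09 (list adjusted p = 0.0129, or adjusted p = 0.693 with an estimated correlation). Markers of other cell types moved too: the fibroblast and endothelial genes rose in 6 of 8, PDGFRB by 0.72 ± 0.07, and TAGLN and ENG fell (list adjusted p = 0.0273, or adjusted p = 0.15 with an estimated correlation). The leukocyte gene PTPRC stood at 2.05 ± 0.34 CPM against 0.59 ± 0.1 and LYZ at 3.59 ± 0.51 against 2.16 ± 0.24, both higher with etoposide.

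Over all genes 3156 were higher and 3355 lower with etoposide in MDA-MB-231, and 538 changed over 2-fold. Without a low-count filter 3682 were higher and 3209 lower. The largest rises were TMEM40 (2.66 ± 0.21, adjusted p = 3.58e-07), LUARIS (2.24 ± 0.25), CDH1, MISP (2.19 ± 0.24), the Notch ligand DLL4 (2.18 ± 0.14), LRRC15 (2.10 ± 0.25), the dynein DNAH10 (2.09 ± 0.18) and LGALS9B (2.02 ± 0.22, uncertain because of copies). The largest falls were the teneurin TENM1 (-1.95 ± 0.09, adjusted p = 5.46e-09), the neuroligin NLGN1 (-1.84 ± 0.09), FGF13 (-1.74 ± 0.32), MIR99AHG (-1.50 ± 0.23), the adhesion molecule DSCAM (-1.50 ± 0.13), TENM2 (-1.40 ± 0.11), the glypican GPC6 (-1.35 ± 0.09) and the kinase MAP2K6 (-1.32 ± 0.14). TENM1 was at 20.9 ± 0.49 CPM with etoposide and 80.8 ± 4.4 with interferon-γ. DESeq2 called 2435 genes in MCF-7 and 4565 in MDA-MB-231, against 4331 and 6511 by edgeR.

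**Figure D4:**
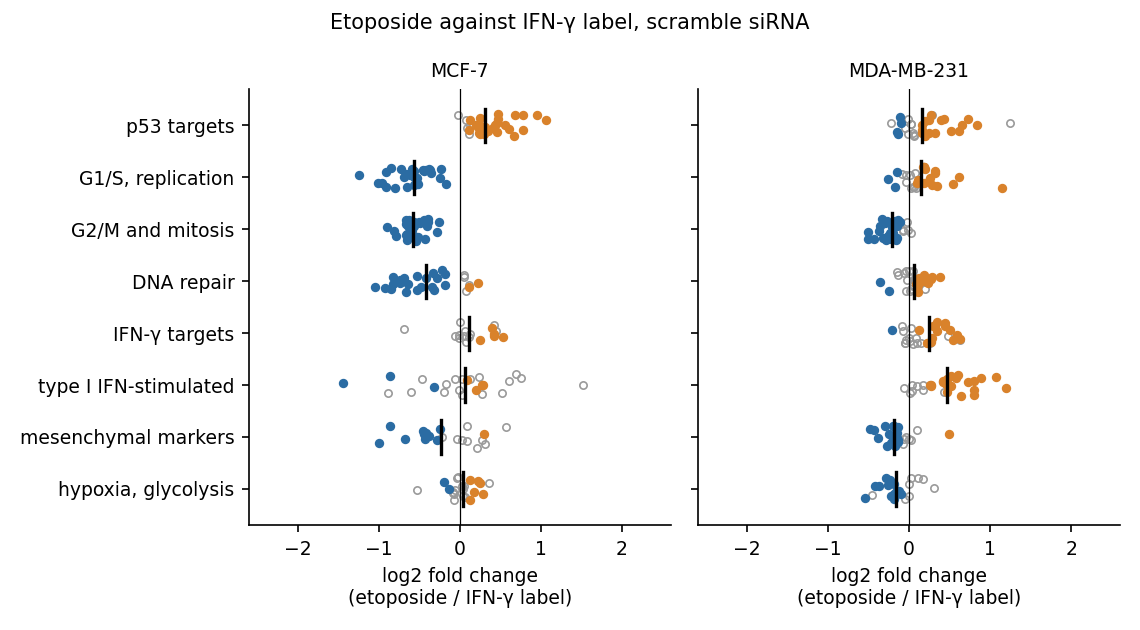
Log2 fold change of etoposide over interferon-γ in scramble cells for each tested gene of 8 lists in MCF-7 and MDA-MB-231; filled points passed an adjusted p of 0.05 (orange higher, blue lower), open points did not, and black bars are medians. The G1/S median is -0.57 in MCF-7 and 0.15 in MDA-MB-231.

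The drug contrast itself differed between the lines in 5106 of 17101 genes, 2536 higher and 2570 lower in MCF-7. This balance depended on the fit, with 1704 higher and 2964 lower without a low-count filter and 1643 and 2189 by DESeq2. DNA replication genes had the strongest evidence of a lower value in MCF-7: E2F2 (-2.37 ± 0.08, adjusted p = 5.55e-17), E2F8 (-1.63 ± 0.07), CLSPN (-1.22 ± 0.05) and EXO1 (-1.34 ± 0.06), with GPRIN1 (-1.06 ± 0.05). Higher in MCF-7 were the ferrireductase STEAP3 (0.88 ± 0.05, adjusted p = 5.3e-12), the phosphatase PTPRK (0.95 ± 0.06), ZMIZ1 (0.68 ± 0.05), DOP1B (0.86 ± 0.07) and CD22 (1.75 ± 0.13). All 28 G1/S genes differed downward (median -0.73, adjusted p = 7.63e-51, or adjusted p = 0.000736 with an estimated correlation) and 20 of 27 DNA repair genes (median -0.58, adjusted p = 1.35e-15, or adjusted p = 0.0133 with an estimated correlation), with TOP2B and LIG4 upward. Of 33 p53 targets 14 differed upward, such as TNFRSF10B and MDM2, and 4 downward, KITLG, PHLDA3, SUSD6 and CDKN1A (median 0.21, adjusted p = 0.00204, or adjusted p = 0.0478 with an estimated correlation). G2/M genes differed downward in 22 of 28 (adjusted p = 2.8e-13, or adjusted p = 0.275 with an estimated correlation), and type I interferon-stimulated genes downward in 9 and upward in 3 of 30 (adjusted p = 0.0166, or adjusted p = 0.829 with an estimated correlation). Hypoxia and glycolysis genes differed upward in 8 of 23 (adjusted p = 0.00106, or adjusted p = 0.392 with an estimated correlation). ER chaperones differed upward in 7 of 28 (adjusted p = 0.0246) and ribosomal proteins in 13 of 82 (adjusted p = 0.00193), both at adjusted p = 0.829 with an estimated correlation. Of the genes called in both lines, 497 rose and 665 fell in both, against 340.8 and 499.2 expected, and 879 went in opposite directions. No expected number was worked out for the opposite directions. Across 13886 genes the drug contrasts of the lines had a Pearson correlation of 0.03, with genes not independent replicates.

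The counts were compared with the authors' deposited tables of significant genes. For MCF-7 with etoposide the authors' deposited table holds 456 genes, of which 455 were called here in the same direction, and with interferon-γ 328 genes, of which 326 were. P4HB is listed there at -0.84 and -0.72. For MDA-MB-231 with etoposide the authors' deposited table holds 4 genes, P4HB (0.41), SLC36A1 (0.26), TNKS2 (0.22) and FLG (0.21), all with the opposite sign to the counts, where P4HB was at -0.55, SLC36A1 at -0.40, TNKS2 at -0.28 and FLG at -0.93. The direction of the deposited contrast is not stated. With interferon-γ the authors' deposited table for MDA-MB-231 holds 10 genes, all of the same sign here, and FYCO1 was the 1 called. In the authors' deposited table of gene symbols by direction, 784 of 784 tested symbols listed as lower and 766 of 820 listed as higher in MCF-7 with etoposide had the same sign here, and 723 of 724 and 801 of 876 with interferon-γ. Fewer were called in that direction: 675 lower and 536 higher with etoposide, and 484 lower and 482 higher with interferon-γ. For MDA-MB-231 every tested symbol had the same sign: 53 lower and 27 higher with etoposide, and 10 lower and 25 higher with interferon-γ, of which FYCO1 was called under each drug.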

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

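The tests on other splits of the libraries, on 1 library with weak knockdown, on the size of the MDA-MB-231 changes and on proportion to knockdown were chosen after the result was seen. The results here were picked because a test of the difference between drugs or between lines passed.

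In MCF-7 the P4HB knockdown effect differed between etoposide and interferon-γ in 69 genes. RGS6 had the higher effect with etoposide (0.69), and KIF4A (-0.59), GTSE1 (-0.59), CDC20 (-0.42), PIMREG (-0.84) and DEPDC1 (-0.65) the lower, with a G2/M list median of -0.41. Of 40 splits of the libraries, 4 gave at least 69 genes and the highest other gave 719, so chance was not excluded by this count. Of the 4 splits, 3 keep most labels under one drug and turn most round under the other, so that they measure the sum of the knockdown effects, a structure of the samples. Among the 25 splits that do not do so, 1 was as large, the real one, and the highest other gave 61. In MDA-MB-231 the same difference gave 0 genes in edgeR and 0 in DESeq2, with 714 and 259 at an unadjusted p under 0.05, and 40 of 40 splits gave at least as many, the highest other being 0.

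Between the lines, the knockdown effect with etoposide differed in 556 genes. P4HB itself differed by -0.37. The higher effects in MCF-7 were CAPN2 (0.62), LOXL2 (1.12), DUSP5 (0.80), LAMB3 (0.85) and TGFBR2 (0.50), and the lower ones SPAG5 (-0.50), KIF4A (-0.66), CDCA8 (-0.51), KIF23 (-0.39) and KIF20A (-0.59), with a G2/M list median of -0.45. Of 40 splits 3 gave as many genes, with 1047 in the highest other, and 2 of the 3 measure a sum in the way given above. Among the 17 others 1 was as large, the real one, and the highest other gave 496. These 17 are too few for a share under 0.05, so chance was not excluded for the 556 genes. With interferon-γ 200 genes differed: P4HB by -0.36, LAMB3 by 1.00, DUSP5 by 0.72, TGFBR2 by 0.56, ETV5 by 0.92 and CAPN2 by 0.54 upward, and RAB30 by -0.59, FILIP1L by -0.64, AMOTL1 by -0.30, PHLDB2 by -0.62 and FAM234B by -0.38 downward. Here 6 of 40 splits gave as many, with 543 in the highest other, and among the 21 splits that do not measure a sum 4 did, with 270 in the highest other. Chance was not excluded for this count.

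The contrast of etoposide with interferon-γ in scramble cells differed between the lines in 5106 genes. Higher in MCF-7 were STEAP3 (0.88), PTPRK (0.95), ZMIZ1 (0.68), DOP1B (0.86) and CD22 (1.75), and lower E2F2 (-2.37), E2F8 (-1.63), CLSPN (-1.22), EXO1 (-1.34) and GPRIN1 (-1.06). The list medians were 0.21 for p53 targets, -0.73 for G1/S and DNA replication and -0.58 for DNA repair. Of 40 splits 1 gave as many genes, the real one, and the highest other gave 3367. Since many of the 40 measure a sum in the way given above, they do not settle whether chance gave this count. Among the 17 splits that do not measure a sum 1 was as large, the real one, and the highest other gave 2742, but 17 splits are too few for a share under 0.05.

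For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. The real counts of the knockdown comparisons were 2188 and 1512 in MCF-7 and 2 and 3 in MDA-MB-231, and those of etoposide against interferon-γ 4331 and 6511. The highest other split gave 0 in each of the 6, and 1 of 10 splits, the real one, was as large.

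Many genes passed with P4HB knockdown in MCF-7 and few in MDA-MB-231. A larger spread between MDA-MB-231 libraries as the whole cause is argued against: 1333 genes picked in MCF-7 with interferon-γ and read with etoposide moved by a median of 0.196 (0.189 to 0.209) in MCF-7 and 0.04 (0.034 to 0.046) in MDA-MB-231, where the median SE was 0.05 against 0.047 in MCF-7. These SEs pool the spread over the 12 libraries of a line. The ranges come from resampling the genes with the libraries held fixed, so they hold no spread between libraries. Genes are not independent replicates. Between pairs of replicate libraries, the chi-square per gene was 3.02 to 4.98 in MDA-MB-231 knockdown cells with etoposide. It was at most 2.35 in MCF-7 pairs, so a part played by spread was not excluded. For the same 1333 genes, the medians argue against changes in strict proportion to the P4HB log2 change, with the spread between libraries left out. The ratio of their medians, MDA-MB-231 over MCF-7, was 0.2 (0.17 to 0.23) against 0.59 for P4HB, for which no range was made. It was 0.25 (0.22 to 0.28) against 0.55 for 1944 genes picked with etoposide and read with interferon-γ. All were picked in MCF-7 and none in MDA-MB-231, so genes that answer in MCF-7 alone lower the ratio. A response that needs a deeper knockdown is not argued against. A single library with weak knockdown does not account for the few calls in MDA-MB-231 with interferon-γ, as 11 genes passed without the third knockdown library. What remains was not tested, as the design holds neither a matched knockdown in the 2 lines nor a second siRNA.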

How the results depend on the processing

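The tests with counts summed over transcripts, the longest transcript per gene, genes under 0.3 reads per base and the likelihood ratio test were chosen after the data had been seen. No called value of a named gene, of a list or of P4HB reversed, but the direction with more genes turned in some fits. Over all alternatives, 404 main counts and P4HB values kept their side of the threshold or stayed within 1.5 times. Another 89 moved more and 12 lost a call. Fits without 1 library aside, 6320 named-gene values stayed called or uncalled, 60 gained a call and 132 lost one. With DESeq2 size factors every gene count stayed within 1.5 times (2192, 1497, 2, 3, 71, 0, 530, 200, 4360, 6445 and 4959). Of 381 named-gene calls the Wald test kept 316. Unless a smaller number of libraries or genes explains it, the cause was not tested.

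The DESeq2 Wald test gave 961 and 592 knockdown calls in MCF-7, 13 and 5 in MDA-MB-231, 2435 for the drugs in MCF-7, 423 genes shared between the drugs in MCF-7 and 3 of the genes in the authors' deposited table for MDA-MB-231 with interferon-γ. With an estimated correlation the lists passing were 0 and 0 for knockdown in MCF-7, 0 and 1 in MDA-MB-231, 1 and 0 for the difference between drugs in MCF-7 and MDA-MB-231, 1 and 0 for the difference between lines with etoposide and interferon-γ, 0 for the drugs in MDA-MB-231 and 3 for the line difference of the drugs. Without a low-count filter 32 and 5 knockdown genes passed in MDA-MB-231, 112 for the MCF-7 drug difference, and 3 authors' genes. With at least 50 reads in 3 libraries, the P4HB value of -0.45 in MDA-MB-231 with interferon-γ lost its call (adjusted p = 0.0566) and 1 gene was shared between the drugs. The replicate block gave 1 gene in MDA-MB-231 with etoposide, P4HB at -0.45 with interferon-γ (adjusted p = 0.0854) and 0 shared genes in edgeR. Summed transcripts gave 0 genes in edgeR in MDA-MB-231 with etoposide (1099 at an unadjusted p under 0.05 and 13 by DESeq2 without summing), P4HB at -0.55 (adjusted p = 0.0725) and -0.45 (adjusted p = 0.134), 0 shared genes and 33 for the MCF-7 drug difference. Genes under 0.3 reads per base gave 1, 1 and 42 for the same 3 counts. The likelihood ratio test gave 85 and 42 in MDA-MB-231, 6 shared, 124 for the MCF-7 drug difference, 304 for the line difference with interferon-γ and 3 authors' genes. Only the 6 libraries compared gave 6 genes in MDA-MB-231 with etoposide, P4HB at -0.45 (adjusted p = 0.0967), 1 shared and 2 authors' genes. All 24 libraries in one fit gave 47 and 11, 4 shared and 3 authors' genes. Over these alternatives the P4HB log2 changes kept their sign.

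The balance of directions among genes depended on the fit. For the drugs in MCF-7, 1953 were higher and 2378 lower with etoposide, and 2190 and 2034 with all 24 libraries in one fit. In MDA-MB-231, 3156 were higher and 3355 lower, and more were higher than lower with DESeq2 size factors, the DESeq2 Wald test, no low-count filter (3682 and 3209), at least 50 reads in 3 libraries, summed transcripts, only the 6 libraries compared and all 24 libraries. For the line difference of the drugs, 2536 were higher and 2570 lower, against 1704 and 2964 without a low-count filter, 1643 and 2189 by DESeq2, 2509 and 2508 with the replicate block and 2231 and 2014 for genes under 0.3 reads per base. For knockdown in MCF-7 with etoposide, 1177 were higher and 1011 lower, and 850 and 945 for genes under 0.3 reads per base. For the line difference of knockdown with etoposide, 332 were higher and 224 lower, and 198 and 203 without MCF-7 scramble library 3. For knockdown in MDA-MB-231 with etoposide 1 was higher and 1 lower, against 1 and 12 by DESeq2 and 3 and 71 without P4HB siRNA library 3, and with interferon-γ 2 were higher and 1 lower, against 4 and 7 without P4HB siRNA library 3.

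Leaving out 1 library at a time, counts of knockdown genes ranged from 1319 to 1981 and 849 to 1362 in MCF-7 and from 0 to 74 and 0 to 11 in MDA-MB-231, for the drug difference from 39 to 122 and 0 to 90, for the line difference from 348 to 593 and 109 to 195, for the drugs from 3322 to 4053 and 5269 to 5933, and for their line difference from 4457 to 4885. Lists passing ranged from 10 to 12, 8 to 11, 4 to 8 and 4 to 11 for knockdown, 3 to 6 and 2 to 7 for the drug difference, 5 to 9 and 3 to 6 for the line difference, 4 to 6 and 10 to 14 for the drugs and 7 to 8 for their line difference. Genes shared between the drugs ranged from 668 to 922 and 0 to 2, and authors' genes from 448 to 455, 313 to 323, 0 to 0 and 0 to 1. P4HB ranged from -0.97 to -0.90, -0.85 to -0.79, -0.58 to -0.52 and -0.57 to -0.39. Counts moved over 1.5 times without these libraries. MCF-7 with etoposide: P4HB siRNA 3 (1319, and 348 for the line difference). MCF-7 with interferon-γ: scramble 3 (951) and P4HB siRNA 2 (849), and for the line difference scramble 2 and 3 (126 and 109) and P4HB siRNA 2 and 3 (117 and 128). MCF-7 drug difference: scramble etoposide 1 and 2 (43 and 41), scramble interferon-γ 3 (43) and P4HB siRNA etoposide 1, 2 and 3 (39, 122 and 40). MDA-MB-231 with etoposide: scramble 2 and 3 (0 and 1), P4HB siRNA 1, 2 and 3 (0, 1 and 74). MDA-MB-231 with interferon-γ: scramble 1, 2 and 3 (0, 1 and 0), P4HB siRNA 1 and 3 (0 and 11). Counts of lists moved over 1.5 times without P4HB siRNA 1 for knockdown in MDA-MB-231 with etoposide (8) and P4HB siRNA 3 with interferon-γ (4), without scramble etoposide 1 for the drug difference in MCF-7 (6), without scramble etoposide 2 (5) and P4HB siRNA interferon-γ 1 and 2 (7 and 6) for that in MDA-MB-231, and, for the line difference, without MDA-MB-231 scramble 1 or P4HB siRNA 1 with etoposide (5 and 5) and scramble 2 with interferon-γ (3). The drug difference in MDA-MB-231 gave 90 genes without P4HB siRNA etoposide 3. P4HB lost its call in MDA-MB-231 with etoposide without scramble 2 (adjusted p = 0.114) or P4HB siRNA 1 (0.0565), and with interferon-γ without scramble 1, 2 or 3 (0.126, 0.0727 and 0.239) or P4HB siRNA 1 or 2 (0.126 and 0.16).

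The deviations from the group means of libraries with the same experiment number had a correlation over 0.1 in 9 of 18 pairs in MCF-7 (median 0.0495, against -0.0075 for other pairs) and in 2 of 18 in MDA-MB-231 (median -0.026, against 0.019), and 5 of 12 and 0 of 12 libraries were closest to their own number. The sources used here do not say whether a number marks cultures handled together, so pairing was left open. The block changed no other main count by over 1.5 times and no other P4HB call. At a depth of 8.9 to 11.37 M reads at gene level with 3 libraries per group, 47.8% and 58.2% of genes changed by 0.25 were recovered in simulated data, and depth itself was not varied.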

Other observations

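The tests of ERK targets, of genes shared by both lines, of the drug labels and of the spread of abundant genes were chosen after the results were seen.

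Some genes moved with P4HB knockdown in both lines. Of genes called in the same direction under both drugs in MCF-7, 39 of 516 were also higher in MDA-MB-231 at an unadjusted p under 0.05 under both drugs, against 4 expected, and 45 of 366 lower, against 2.4 expected. The opposite direction held 0 and 1 genes. The counts include pairs such as GALNT4 and POC1B-GALNT4, which had nearly the same values and may share reads. With no second siRNA, effects of the siRNA other than through P4HB could not be tested. The following genes were chosen after their values were seen, with log2 changes for MCF-7 with etoposide and interferon-γ and then MDA-MB-231 with the same. Higher were KDELR3, a receptor that returns proteins to the endoplasmic reticulum (0.38, 0.40, 0.21, 0.12), the cytokine receptor IL6R (0.69, 0.67, 0.42, 0.59), the growth factor MDK (0.51, 0.59, 0.17, 0.32), IGFBP3 (0.42, 0.54, 0.17, 0.15) and the autophagy gene WIPI1 (0.30, 0.17, 0.18, 0.16). Lower were CALCR (-0.89, -1.02, -1.66, -0.99), the lysosomal amino acid transporter SLC36A1 (-0.34, -0.37, -0.40, -0.34), the tankyrase TNKS2 (-0.36, -0.44, -0.28, -0.19), RMDN3 (-0.53, -0.48, -0.28, -0.18) and the mitochondrial transcription factor TFAM (-0.29, -0.22, -0.12, -0.12). Each of these 10 was called in MCF-7 and none passed an adjusted p of 0.05 in MDA-MB-231 with edgeR.

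Genes used as readouts of ERK signalling were read because DUSP5 and ETV5 had been seen to rise, so the count is no test of the pathway. Of 11 genes, a textbook signature with DUSP5 added, 6 rose, 0 fell and 5 did not pass in edgeR under each drug in MCF-7, with medians of 0.37 and 0.43: SPRY4 (0.87 and 1.01), ETV5 (0.71 and 0.89), DUSP5 (0.78 and 0.66), ETV4 (0.57 and 0.51), DUSP4 (0.37 and 0.43) and EPHA2 (0.15 and 0.18). In MDA-MB-231 0 of 11 passed in edgeR, with medians of -0.01 and -0.05.

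Interferon gamma targets were not higher in the libraries labelled interferon-γ in either line. In MCF-7 a swap of the drug labels is argued against, since p53 targets were higher in the libraries labelled etoposide by a median of 0.31, and in MDA-MB-231, where interferon gamma targets were higher by a median of 0.24 in the libraries labelled etoposide, a swap cannot be told apart from other causes. Other measures in MDA-MB-231 ran the way the labels say: with the etoposide label p53 targets were higher in 16 of 31 (median 0.17, adjusted p = 0.00079, or adjusted p = 0.0971 with an estimated correlation) and G2/M genes lower in 23 of 28 (median -0.21, adjusted p = 1.11e-11, or adjusted p = 0.15 with an estimated correlation), and CD274 was higher with the interferon-γ label (86.5 against 74.8 CPM). The question stays open because the lists point both ways and TP53 is mutated in that line. Missing transcripts of the pathway are argued against: of IFNGR1, IFNGR2, JAK1, JAK2 and STAT1, the lowest mean over the 12 libraries of a line was 29.2 CPM (JAK2 in MDA-MB-231), and the lowest mean of a group was 27.6 CPM (IFNGR2 in MCF-7 scramble cells with interferon-γ). An interferon-γ treatment that was absent or inactive may remain: GBP1, CXCL10, IDO1 and CIITA did not exceed 0.31 CPM in any MCF-7 group, and with no untreated group this cannot be told apart from a line that does not respond. GBP1 stood at 69 and 68.2 CPM with etoposide and interferon-γ in MDA-MB-231. In the same scramble groups CIITA was at 39.9 and 36 CPM, but IDO1 at 0.219 and 0.163 and CXCL10 at 0.609 and 0.658. An absent or inactive treatment was thus left open in this line too.

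Genes at 0.2 to 0.8 reads per base varied less between replicates, by the median, than read counting allows, and genes above 0.8 varied more. In genes matched on their number of reads, the median spread index (1 for read counting) was 0.74 (0.7 to 0.78) for 454 genes at 0.45 to 0.6 reads per base and 1.92 (1.78 to 2.11) for 339 genes under 0.1. The ranges come from resampling genes. Among genes matched on reads, those with more reads per base have shorter transcripts, so transcript length cannot be told apart from reads per base here. The removal of duplicate reads, which caps the counts of genes with many reads per base, may be a cause, and no biological explanation was tested. The matched index rose again to 0.88 at 0.6 to 0.8 and 2 above 0.8 reads per base (3.78 without matching), which a cap alone does not give. P4HB, at about 0.6 reads per base, had an index of 5.19.

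No library looked like a copy of another: over the 24 pairs within groups the chi-square per gene was 0.74 to 4.98 and the highest share of identical counts was 2.6%.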
